A study of Homo sapiens with 6 samples.

How the data were processed

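Gene expression was measured in 6 tissues of EPI-200, a commercial reconstructed human epidermis in which keratinocytes form a layered, cornifying sheet. Per the labels, 3 tissues received 0 Gy and 3 received 0.5 Gy of alpha particles, and all were harvested 4 h later, from 3 independent experiments with a separate tissue for each data point. Total RNA was amplified and labelled with Cy3 and hybridised to 1-colour Agilent whole-genome arrays, 1 tissue to an array. The labels disagree in places: the treatment fields and titles give alpha particles and 0.5 Gy, whereas the sample descriptions speak of protons and give the irradiated tissues another dose. The series title speaks of bystander responses, but no label says which part of a tissue was harvested. Groups were taken from the sample titles, which match the treatment fields.

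The deposited values are spot intensities on a linear scale. Per the submitters' processing notes, they came from Agilent Feature Extraction 9.1.3.1. Per the file headers, the processed signal was made with spatial and multiplicative detrending switched on and global background correction switched off, and the software flagged outlier spots, saturated spots and spots well above background. No normalization between arrays is recorded. The deposited series value table was set against the scanner files spot by spot: all 45015 rows equalled the processed signal on every array, so the table is linear, uncentred and without a direction. Its medians were 46.8, 62.8 and 78.8 for 0 Gy replicates 1, 2 and 3, and 58.8, 56.4 and 60.2 for 0.5 Gy replicates 1, 2 and 3. The flags used were those for control spots, spots well above background, saturation, non-uniformity and population outliers, all set by the authors' scanner software.

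Each array held 45015 spots, of which 1639 were control spots and were left out, which left 41000 distinct probes. The processed signal was divided by the 75th percentile of the array's non-control spots, values below a log2 of -6 were set to that floor, and log2 was taken. The 75th percentile was an intensity of 310, 437 and 542 on the 0 Gy arrays and 411, 395 and 397 on the 0.5 Gy arrays. Spots flagged as outliers were treated as missing, and spots of a probe were averaged. A probe counted as well above background on an array when at least 50% of its spots were. It was tested when this held on at least 3 of the 6 arrays, whatever their group, and when it was unflagged on at least 2 arrays of each group. This gave 26779 tested probes, 65.3% of all. Between 63.0% and 67.5% of probes were well above background on each array, and 0 spots were saturated. Arrays give no count depth, and their number limits the precision.

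Probes were named through the table of RefSeq genes provided for assembly GRCh38.p14, which was used for names only. By accession 23680 probes were named and by symbol or unambiguous synonym another 3930, while 13390 had no current symbol. For a gene with several tested probes, the probe with the highest mean over all 6 arrays stood for the gene, which gave 13915 genes. X-inactivation and Y-linked probes were counted in the tests and are not printed.

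The comparison of 0.5 Gy with 0 Gy was fitted per probe with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Errors of differences are limma standard errors. For a gene not well above background on any array of a group, the fold is a lower bound: the bright group's mean against the dim group's mean after each dim value was raised to the lowest signal well above background on its array. Such a bound carries no error and holds for the main processing only. Gene lists were fixed before the data were examined: 30 lists for the radiation response, stress and inflammation, epidermal layers, metabolism and cell types that a keratinocyte tissue should lack. A list needed 5 tested genes, and 29 qualified. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it, and adjusted over the 29 lists.

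The genes to be named were also fixed before the data were examined. They are, in each direction, the 15 genes with the largest difference among those past the threshold whose groups do not overlap, and for each list up to 4 members with the smallest p, those past the threshold first. Some genes under this rule are counted and not named. Unnamed probes and placeholder symbols are counted and not named. Members outside this rule are named only where a count is 5 or fewer or where the text says that they were chosen after their values were seen.

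Slide and scan were read from the files. Slide 1 held the 3 arrays of 0 Gy and replicate 1 of 0.5 Gy, and slide 2 held replicates 2 and 3 of 0.5 Gy, each slide with a scan of its own, so slide and dose overlap in part. The dose effect was therefore also fitted with slide as a fixed block, with slide as a random block, and within slide 1 alone. Other alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, no filter on dim probes, a filter on all 6 arrays, outlier spots kept, a replicate block, eBayes with trend and robust, array quality weights, an unadjusted p of 0.001, each array left out in turn and, for lists, the mean of a gene's probes. A floor at a log2 of -8 was added after the data were seen.

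The fits were tested on simulated data: 10 draws of 26779 probes for the comparison of 0.5 Gy with 0 Gy, with real probe means, spreads drawn from the fitted prior and 200 changed probes. At a log2 change of 1 the fit without a block called 14.2% of the changed probes, and at a log2 change of 2 it called 79.2%. Of its calls, 4.2% were false. These draws held no slide difference, so this share does not cover false calls from the overlap of slide and dose. With slide as a fixed block and simulated slide differences of SD 0.5, the median estimates were 0.99 and 1.98 for changes of 1 and 2. In these draws 0 probes were called. Their spreads came from the fit without a block, which already holds slide differences among the 0.5 Gy arrays. The fit with the block did call probes in the real data, so these draws do not give its power there. A list of 33 genes shifted by 0.5 was called in 10 of 10 draws, with 1 call in all among the other 28 lists. The simulated genes varied independently and without a slide difference here. These draws therefore do not cover lists whose genes vary together.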

Results

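The response of reconstructed human epidermis to alpha particles was measured at 4 h after exposure to 0.5 Gy, against tissues given 0 Gy, with 3 tissues and 3 arrays per dose. The 75th percentile of the array intensities lay between 310 and 542. Correlations of log2 signals across probes were 0.985 to 0.991 between arrays of 0 Gy, 0.972 to 0.987 between arrays of 0.5 Gy and 0.963 to 0.980 between doses. The first principal component, with 51.3% of the variance, separated the doses: the 0 Gy arrays scored -47.8 to -39.5, and the 0.5 Gy arrays scored -0.24 for replicate 1, 67.1 for replicate 2 and 60.3 for replicate 3. Replicate 1 of 0.5 Gy shared slide 1 with the 0 Gy arrays, while replicates 2 and 3 were on slide 2.

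**Figure D1:**
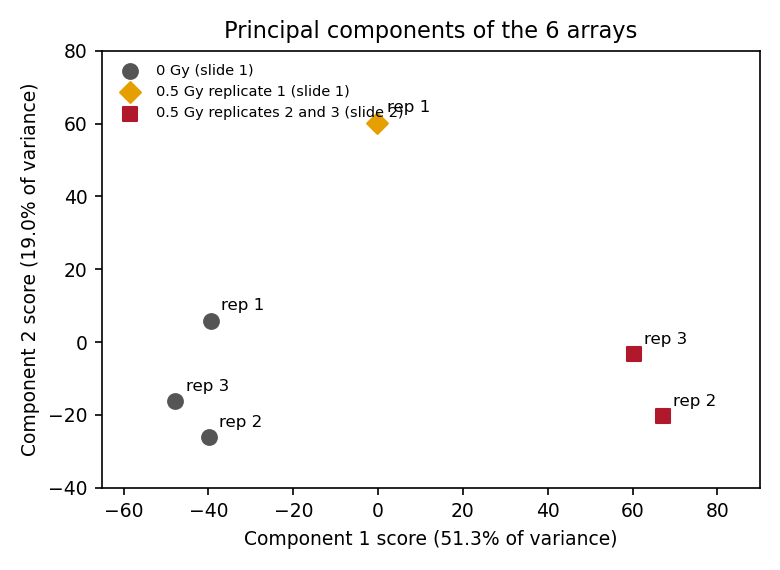
Scores of the 6 arrays on the first principal component (horizontal, 51.3% of variance) and the second (vertical, 19.0%), with 1 point per array. The 0 Gy arrays score below -39 on the first component, replicate 1 of 0.5 Gy lies near 0, and replicates 2 and 3 of 0.5 Gy lie above 60.

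At 0.5 Gy, the largest rises included genes for a sterol hydroxylase, a cytokine and a protease, and the largest falls included interferon-induced genes, although the interferon list as a whole did not pass (adjusted p = 0.069). CH25H, which encodes cholesterol 25-hydroxylase, was higher by 2.94 ± 0.29 on the log2 scale (SE, limma adjusted p = 0.020), and GDF15, a stress-induced cytokine of the TGF-beta family, by 2.51 ± 0.55 (adjusted p = 0.049). The protease gene MMP3 rose by 2.21 ± 0.35, and the apoptosis inhibitor gene BIRC3 was 3.99-fold higher (log2 SE 0.16), and CYP26B1, whose product degrades retinoic acid, rose by 1.78 ± 0.35. Among the falls, G0S2, which encodes an inhibitor of triglyceride lipase, changed by -3.78 ± 0.39, the interferon-induced genes IFIT1, IFI27, MX1 and IFITM1 by -3.03 ± 0.37, -2.38 ± 0.36, -2.21 ± 0.33 and -2.16 ± 0.25, and CYP1B1, a cytochrome P450 gene, by -2.57 ± 0.25. In all, 631 probes were higher and 1027 lower of the 26779 tested, 38.1% and 61.9% of the 1658 calls. By their brightest probe, 359 genes were higher and 460 lower.

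The remaining genes with the largest rises were TMEM217 at 2.16 ± 0.25, KLHDC7B at 2.08 ± 0.31, CREB5 at 2.21 ± 0.43 and RGMA at 2.03 ± 0.45. CREB5 and RGMA were well above background on only 1 of the 3 arrays at 0 Gy. For 6 risen genes no array at 0 Gy was well above background, so only bounds under the main processing are given, without an error. SLC6A13, a GABA transporter gene, was at least 5.69-fold higher, SPOCD1 at least 4.87-fold and the olfactory receptor gene OR1A2 at least 4.70-fold. GDF3 was at least 4.08-fold higher, the neutrophil chemokine gene CXCL8 at least 3.49-fold and the lectin receptor gene CD302 at least 2.76-fold. Over the alternatives the smallest log2 differences of these 6 genes were 0.34 to 0.75. Other genes with large falls were the oestrogen receptor gene GPER1 at -2.33 ± 0.27, PPM1K at -2.32 ± 0.30 and the RNA helicase gene MOV10 at -2.14 ± 0.18. PPM1K and MOV10 were well above background on 2 of the 3 arrays at 0.5 Gy. ZNF556 was at least 10.2-fold lower, the interferon-induced gene IFI44 at least 9.63-fold, NOL4 at least 5.39-fold, KLHL3 at least 4.34-fold and the transcription factor gene ISL1 at least 4.25-fold, with 0 arrays of 0.5 Gy well above background. These bounds too hold for the main processing, and the smallest log2 differences over the alternatives were -1.26 to -0.53. Second probes differed for SLC6A13 (0.71, adjusted p = 0.323) and TMEM217 (-0.26, adjusted p = 0.743), while both probes of IFI27 passed.

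**Figure D2:**
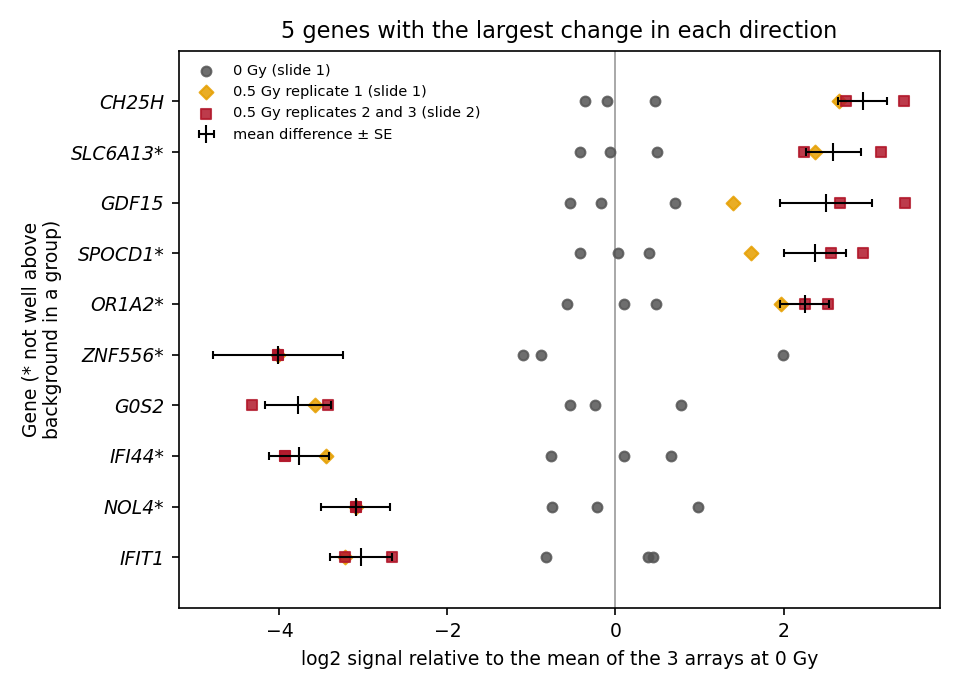
Log2 signal of the 5 genes with the largest difference in each direction, per array, relative to the mean of the 3 arrays at 0 Gy (horizontal), with the mean difference and its SE in black. Grey points are 0 Gy, orange points replicate 1 of 0.5 Gy on slide 1 and red points replicates 2 and 3 on slide 2. Genes with a star were not well above background in a group, and their position is no estimate of the fold. The genes were chosen among those whose groups do not overlap, so by that choice no array of 0.5 Gy lies inside the range of the 0 Gy arrays.

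The test was limma with Benjamini-Hochberg adjustment, and 8082 probes had an unadjusted p under 0.05. The groups did not overlap for 9632 probes, 36.0% of those tested, where chance gives 10%. Slide and dose overlap: with slide as a fixed block 197 probes passed, 67 of them among the 1658, with slide as a random block 323 passed, and within slide 1 alone 131 passed. Slide 2 holds no array of 0 Gy, so every value given with slide as a fixed block or within slide 1 rests on a single irradiated array, replicate 1 of 0.5 Gy. Over the 1658 probes the median absolute log2 difference was 0.97 (median SE 0.17) without a block and 0.86 (median SE 0.21) with the fixed block. The size kept is favoured by selection, because the groups did not overlap in any of these probes and replicate 1 therefore lay outside the range of the 0 Gy arrays. These values therefore cannot show that the difference holds apart from slide. On 500 probes chosen without replicate 1, its median shift against a left-out 0 Gy array was 0.33 to 0.52. The slide 2 arrays differed by a median of 1.59 to 1.63 on those probes. The count also rested on single arrays. It was 0 without any of the 0 Gy replicates 1, 2 and 3 or without 0.5 Gy replicate 3 (7154, 5367, 5103 and 5807 probes at an unadjusted p under 0.05), 27 without 0.5 Gy replicate 2 and 6384 without 0.5 Gy replicate 1. Without 0.5 Gy replicate 1, all 0 Gy arrays lay on slide 1 and all 0.5 Gy arrays on slide 2. Dose and slide were then the same contrast, so the 6384 calls cannot be ascribed to dose. Of the 66 named genes that passed, 9 also passed with slide as a fixed block, among them BIRC3, CD302, CYP1B1, PPM1K, ISL1, MOV10, KLHL3 and RNASE7.

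Genes activated by p53 were higher as a list at the preset correlation (camera adjusted p = 6.1e-04), but not with an estimated correlation (adjusted p = 0.553). The estimate was 0.014, near the preset of 0.01, so the lost call does not stand for strong correlation between these genes. This holds for the p53 list only. For the other called lists the estimate was 0.099 (NF-kB), 0.22 (granular and cornified layer), 0.29 (immediate early), 0.50 (ribosomal) and 0.85 (mitotic). With fry the p53 list passed (adjusted p = 0.017). Of 33 tested, 6 rose, 2 fell and 25 did not pass by their brightest probe, with a median log2 difference of 0.40; adjusted over the list alone, 13 rose and 2 fell. The risen genes included GDF15, TIGAR (1.12 ± 0.16), which encodes a regulator of glycolysis, the p53 ubiquitin ligase gene MDM2 (0.92 ± 0.16) and the translesion polymerase gene POLH (0.88 ± 0.13). PLK2 (0.74 ± 0.16) and the death receptor gene TNFRSF10B (0.69 ± 0.14), chosen after their values were seen, rose as well. TP53I3 fell by 0.94 ± 0.18 and BAX by 0.79 ± 0.18 on the log2 scale. Probes disagreed for MDM2, whose second probe gave 0.20 (adjusted p = 0.473), and for BAX, whose other probes gave 0.74 and 0.05 and did not pass. CDKN1A, chosen after its values were seen, differed by 0.80 (adjusted p = 0.083) at its brightest probe and by 1.08 (adjusted p = 0.040) at another. Within slide 1 the list median was 0.56, and with slide as a fixed block the adjusted p was 5.2e-05, both for replicate 1 of 0.5 Gy alone.

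Genes of the NF-kB pathway and inflammatory cytokines were higher with a median of 0.59 and an adjusted p of 1.6e-04, or 0.859 with an estimated correlation. Of 27 tested, 8 rose, 0 fell and 19 did not pass; adjusted over the list alone, 12 rose. Besides BIRC3 and CXCL8, these included RELB, an NF-kB subunit gene (1.37 ± 0.17), the chemokine gene CXCL1 (1.43 ± 0.21) and the mitochondrial superoxide dismutase gene SOD2 (0.79 ± 0.12). With slide as a fixed block, where replicate 1 of 0.5 Gy stands alone, the median was 0.27 and the adjusted p 0.0026. Immediate early genes were higher with a median of 0.46 and an adjusted p of 0.0028, or 0.865 with an estimated correlation. Of 32 tested, 6 rose, 1 fell and 25 did not pass by their brightest probe. NR4A3, a nuclear receptor gene, rose by 1.73 ± 0.27, and the AP-1 genes FOSL1 and JUND by 1.55 ± 0.28 and 0.76 ± 0.13, while JUN fell by 0.80 ± 0.16. Other probes of NR4A1 and KLF6, chosen after their values were seen, differed by 2.74 and -0.57 (adjusted p = 0.022 and 0.045). Adjusted over the list alone, 11 rose and 1 fell. This shift did not pass with slide as a fixed block (median 0.32, adjusted p = 0.183).

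Interferon-stimulated genes did not pass as a list, and single members went both ways. Of 26 tested, 4 fell (IFI44, IFIT1, IFI27 and MX1), ISG20 rose by 0.72 and 21 did not pass by their brightest probe. Adjusted over the list alone, 3 rose and 5 fell. The median was -0.43 and the adjusted p 0.069, and the list passed in 4 of 22 alternatives. Within slide 1 the differences of IFIT1, IFI27 and MX1 were -3.22, -2.91 and -2.66, while the list median there was 0.06. ISG15, an abundant interferon-induced gene chosen after its values were seen, differed by -0.50 and did not pass. Another probe of IFI6, also chosen after its values were seen, differed by -1.99 (adjusted p = 0.022), while its brightest probe did not pass.

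**Figure D3:**
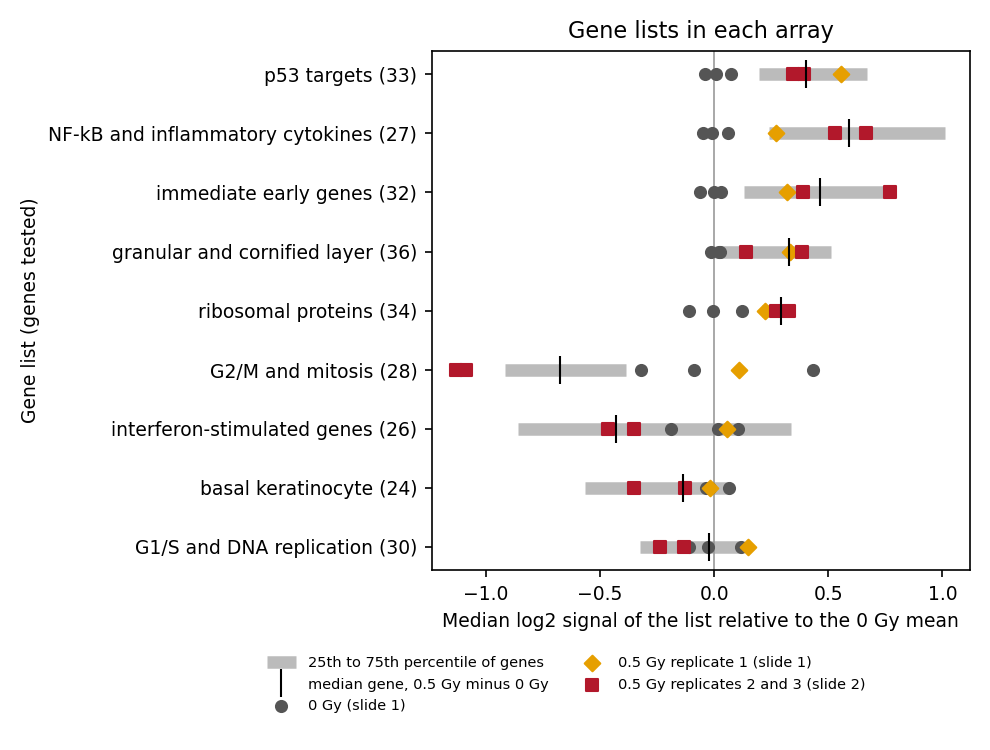
Median log2 signal of 9 gene lists in each array, relative to the mean of the 0 Gy arrays (horizontal); black bars are the median gene difference between doses and grey bands its 25th to 75th percentile over genes. The p53 list lies above all 0 Gy arrays in each array of 0.5 Gy, at 0.35 to 0.56. The mitotic list is at 0.11 in replicate 1 of 0.5 Gy and at -1.09 and -1.13 in replicates 2 and 3.

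Mitotic genes were lower as a list, but their median was not lower in every irradiated tissue. The list median was -0.67 and the camera adjusted p 5.5e-05, or 0.871 with an estimated correlation. That estimate was 0.854 against the preset of 0.01, so the smaller p treats genes that vary together as nearly independent. By their brightest probe all 28 tested genes had a negative difference. Only TPX2, a spindle assembly gene, passed by itself, at -0.91 ± 0.16, also adjusted over the list alone. CENPE, KIF11 and HMMR had differences of -0.92, -0.92 and -1.25 and did not pass. A second KIF11 probe had the opposite sign (0.20, adjusted p = 0.515). Within slide 1 the differences of TPX2, CENPE, KIF11 and HMMR were -0.66, -0.53, -0.53 and -0.33, unlike the list median there. These genes were chosen by smallest p over all arrays, which favours members that are low in replicate 1 too. The list median relative to 0 Gy was -1.09 and -1.13 in replicates 2 and 3 and 0.11 in replicate 1, inside the range of the 0 Gy arrays of -0.32 to 0.43. With slide as a fixed block the direction turned (median 0.11, adjusted p = 0.920). Of 30 genes of G1/S and DNA replication only the cyclin gene CCNE1 passed by its brightest probe, at 0.96 ± 0.18, with a list median of -0.02 (adjusted p = 0.679) that became 0.01 with normexp correction and 0.15 with slide as a fixed block. A second probe of the flap endonuclease gene FEN1, chosen after its values were seen, fell by 1.36 (adjusted p = 0.038), while its brightest probe did not pass (-0.90). Among 25 genes of double-strand break repair, MDC1 (-1.38 ± 0.28) and RBBP8 (-0.68 ± 0.15) fell and the list did not pass (median -0.11, adjusted p = 0.061). It passed in 6 of 22 alternatives, among them without 0.5 Gy replicate 1 (median -0.37, camera adjusted p = 0.0026), and its median was 0.07 within slide 1. Without 0.5 Gy replicate 1 dose and slide were the same contrast, so that result cannot separate them. Replication-dependent histone genes did not pass as a list, with a median of 0.11 over 23 genes and 1 fallen, H4C3 (adjusted p = 0.680 for the list).

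In the epidermal layers, genes of the granular and cornified layer were higher as a list (median 0.33, adjusted p = 0.0041), but the adjusted p was 0.865 with an estimated correlation and 0.528 after quantile normalization, where the median was 0.05. Of 36 tested, 4 rose and 0 fell: the cornified envelope genes SPRR2E by 0.91 ± 0.13, CNFN by 0.88 ± 0.13, LCE3D by 0.71 ± 0.14 and LCE2C by 0.66 ± 0.13. Adjusted over the list alone, 6 rose. In replicate 1 of 0.5 Gy alone, with slide as a fixed block, the median was 0.33 and the adjusted p 0.0095. Suprabasal genes did not pass (20 tested, adjusted p = 0.680); the differentiation factor genes GRHL3 and OVOL1 rose by 1.29 ± 0.26 and 1.24 ± 0.25, and the list median of 0.17 became -0.04 after quantile normalization. Basal keratinocyte genes had a median of -0.14 over 24 genes (adjusted p = 0.061) and did not pass: 3 fell, among them BMP7 by 1.19 ± 0.17 and TP63, the master regulator of stratified epithelia, by 0.79 ± 0.15, and adjusted over the list alone 7 fell and 1 rose. After quantile normalization the basal median was -0.41 and the list passed (adjusted p = 0.0054), as it did in 7 of 22 alternatives. Antimicrobial and wound keratin genes did not pass (median 0.27 over 17, adjusted p = 0.218), with the ribonuclease gene RNASE7 higher by 0.98 ± 0.20; in replicate 1 of 0.5 Gy alone, with slide as a fixed block, their median was 0.40 and the adjusted p 0.016. Among 24 matrix and protease genes MMP3 rose and 2 fell, among them MMP9 by 1.52 ± 0.23 (median 0.15, adjusted p = 0.855).

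Ribosomal protein genes were higher as a list without any single call. Of 34 tested, 32 had positive differences (median 0.29, adjusted p = 0.0014, or 0.871 with an estimated correlation), but the median was -0.0032 and the adjusted p 0.725 after quantile normalization. With slide as a fixed block the median was 0.22 and the adjusted p 0.031, for replicate 1 of 0.5 Gy alone. Lists of other stress and metabolic programmes did not pass. Metallothionein genes had a median of -0.15 (12 tested, adjusted p = 0.680), which was 0.52 in replicate 1 of 0.5 Gy and -0.34 and -0.80 in replicates 2 and 3; with slide as a fixed block, and so for replicate 1 alone, the adjusted p was 0.013. Single calls by the brightest probe were DNAJA1 (0.96 ± 0.14) among 22 heat shock genes (adjusted p = 0.384), DDIT4 (-1.04 ± 0.18) and CEBPB (0.87 ± 0.19) among 31 genes of the unfolded protein and ATF4 response (adjusted p = 0.680), ADM (0.65 ± 0.14) among 28 hypoxia and glycolysis genes (adjusted p = 0.754), and BAMBI (1.06 ± 0.15) among 21 TGF-beta targets (adjusted p = 0.680), where 5 rose and 2 fell adjusted over the list alone. In the hypoxia list, other probes of P4HA2 and EGLN1 fell by 2.31 and 0.62 and another probe of PFKFB3 rose by 1.38, genes chosen after their values were seen. Over all lists, 13 genes had such a call where the brightest probe did not pass, 3 higher and 10 lower. The clock genes NR1D2 and CRY1 rose by 1.14 ± 0.20 and 0.92 ± 0.18 within a list of 18 at a median of 0.00 (adjusted p = 0.855), although a second NR1D2 probe passed in the opposite direction (1.99-fold lower, adjusted p = 0.028); the median was -0.07 after quantile normalization. The glucocorticoid target KLF9 fell by 0.95 ± 0.14 among 16 (adjusted p = 0.844).

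No gene passed among NRF2 targets (26 tested, median 0.19, adjusted p = 0.855), cholesterol biosynthesis (25, median 0.17, 0.346) or the mitochondrial respiratory chain (30, median 0.13, 0.819), and the medians of these lists were -0.05, -0.05 and -0.11 after quantile normalization. Median, mean and test differed in sign for the unfolded protein response (median -0.08, mean 0.0022, test lower), hypoxia (median -0.01, mean 0.0049, test lower) and glucocorticoid targets (median 0.06, mean -0.04, test lower). Markers of cell types outside the keratinocyte lineage did not pass as lists. The adjusted p was 0.445 for fibroblast markers (8 tested, median -0.22), 0.680 for melanocyte markers (7, median 0.24), 0.346 for myeloid and Langerhans markers (8, median 0.30), 0.680 for lymphocyte markers (8, median 0.24) and 0.243 for Merkel and neural markers (6, median -0.72). Over the alternatives the Merkel and neural median lay between -1.05 and -0.08. The melanocyte median lay between -0.02 and 0.33 and was negative only without 0 Gy replicate 3. With slide as a fixed block, and so for replicate 1 of 0.5 Gy alone, fibroblast markers had a median of -0.38 (adjusted p = 0.048). ISL1 and the neurofilament gene NEFM (-1.28 ± 0.28) were the only markers that passed by their brightest probe, and a second NEFM probe had the opposite sign (0.26, adjusted p = 0.236). Only 4 endothelial markers were tested, too few for the list test, and 0 of them passed, with VWF at 1.15 (adjusted p = 0.097).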

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

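The floor at a log2 of -8 was chosen after the data were seen; the other alternatives were planned. The 1658 calls (631 higher, 1027 lower) became 1671 under quantile normalization, 1918 under median scaling, 2123 with a filter on all 6 arrays, 1543 with outlier spots kept and 1570 with the lower floor; normexp gave 2012 (948 higher). Without a filter on dim probes 833 passed (398 higher, 435 lower), where more probes share the adjustment. With slide as a fixed block 197 passed (118 and 79), as a random block 323 (91 and 232), and within slide 1 alone 131 (83 and 48), where, as in the fixed block, the dose difference rests on a single irradiated array; the called probes had a median absolute log2 difference of 0.97 without and 0.86 with the fixed block, a size that their selection favours. Trend and robust gave 2799 (1276 higher) and array quality weights 8648 (4613 and 4035). At an unadjusted p of 0.001, 753 passed (230 and 523). Leaving out an array gave 0 to 6384 calls (0 to 3513 higher, 0 to 2871 lower), with 6384 only without 0.5 Gy replicate 1, where dose and slide coincide. With the replicate block 0 probes and 9 lists passed, 7915 probes having an unadjusted p under 0.05. Same-numbered arrays deviated from their group means with correlations of 0.094, 0.148 and -0.0049 for replicates 1, 2 and 3, against a pairing threshold of 0.1. Only replicate 2 lies above it, so whether the numbers pair the tissues stays undetermined. The 6 called lists all passed without each array in turn, while 0 passed with an estimated correlation. Of all lists 3 passed with fry: p53 targets and NF-kB among the called, and the Merkel and neural markers, which camera did not call. The mitotic list turned to 0.11 with slide as a fixed block and within slide 1, metallothioneins to 0.52 and G1/S genes from -0.02 to 0.15 in both, each from replicate 1 of 0.5 Gy alone, where the medians of break repair (0.07), interferon (0.06), TGF-beta (-0.07), the clock (-0.18) and the unfolded protein response (0.01) also changed sign; ribosomal proteins turned to -0.0032 under quantile normalization, which removes a trend with brightness. Beyond these cases the cause was not tested. Of the named genes, 3 that had not passed changed sign in some alternative. Of the 66 past the threshold, 59 still passed under quantile normalization, 64 under median scaling, 56 under normexp and 32 with slide as a random block. Without a filter on dim probes 24 passed, with the replicate block 0 and with array quality weights 66. Without any one of the 0 Gy replicates or without 0.5 Gy replicate 3, 0 passed. Without 0.5 Gy replicate 2, 4 passed, and without 0.5 Gy replicate 1, where dose and slide coincide, all 60 that were fitted passed. The authors' value table equals the scanner signal and was not run as an alternative. Probes near background limit the folds of dim genes, which are given as bounds.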

Other observations

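The lists in this part were put together, and the tests on slide, basal cells and cycling cells were chosen, after the results were seen; the splits of the arrays and the brightness-matched lists were set before theirs were. Fallen genes included members of the Wnt pathway. Of 47 ligands, regulators and targets tested, 9 fell and only DKK1, a secreted Wnt inhibitor gene, rose, by 1.44 ± 0.17 on the log2 scale. The fallen genes were SOSTDC1 (at least 2.87-fold lower, not well above background at 0.5 Gy), APCDD1 (-1.61 ± 0.19), the Frizzled ubiquitin ligase genes ZNRF3 (-1.46 ± 0.20) and RNF43 (-1.42 ± 0.15), the ligand genes WNT4, WNT10A and WNT3 (-1.35, -1.25 and -1.14) and the transcription factor genes TCF7L1 and TCF7L2 (-1.20 and -0.61). Over all members 28 differences were negative and 19 positive, with a median of -0.07, and no p is given for lists built after the fallen genes were seen.

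Some interferon-related genes outside the fixed list fell as well. Of 43 tested, 8 fell, 0 rose and 35 did not pass: IFITM1, MOV10 and PARP9 by -2.16, -2.14 and -2.11, TLR3 by -1.64, and GBP2, RNF213, EIF2AK2 and DHX58 by -1.41 to -1.06. The median was -0.26, at -0.25, -0.28 and -0.29 in replicates 1, 2 and 3 of 0.5 Gy, and it was negative under quantile normalization, median scaling and normexp as well. Of 73 olfactory receptor genes tested, 5 rose, 0 fell and 68 did not pass, with a median of 0.29. Of all 13915 genes, 359 were higher and 460 lower by their brightest probe. The olfactory median was 0.19, 0.35 and 0.53 in replicates 1, 2 and 3 of 0.5 Gy, lowest on slide 1. It was 0.30 under quantile normalization and median scaling and 0.18 under normexp. OR1A2, the member with the largest rise, was not well above background on any 0 Gy array.

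The call of 1658 probes was weighed against grouping and slide. Of the 10 splits of the 6 arrays into groups of 3, only the real split called any probe, the highest other count being 0, but 10 splits are too few for a share under 0.05. For the gene lists 6 of the 10 splits called at least the 6 lists of the real split, and the highest other split called 8, so camera at the preset correlation called lists in splits that mix the doses too. On 500 probes chosen from the slide 2 arrays against a pair of slide 1 arrays, each slide 1 array was set against a left-out slide 1 array. Replicate 1 of 0.5 Gy went with the slide 2 arrays on 72.1% of probes on average (64.4% to 82.0%). A 0 Gy array in its place did so on at most 54.7% on average. That average includes the comparison with replicate 1 left out, which mirrors replicate 1's own value and so widens the gap. Set against each other, the 0 Gy arrays went with slide 2 on 24% to 76.0% of probes, with median shifts of -0.25 to 0.25. The median shift was 0.33 to 0.52 for replicate 1, where the slide 2 arrays differed by a median of 1.59 to 1.63. In the comparisons between 0 Gy arrays they differed by 1.44 to 1.54. A slide difference as the whole cause would put replicate 1 level with the controls, but with only 4 arrays on slide 1 the smallest share is 0.25, so slide and dose cannot be told apart for the calls as a whole.

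The median of the mitotic genes was lower in replicates 2 and 3 of 0.5 Gy only. TPX2, CENPE, KIF11 and HMMR were lower in replicate 1 too, at -0.66, -0.53, -0.53 and -0.33. Their choice by smallest p over all arrays favours this, so they do not speak for the list. A loss of basal cells as the whole cause would lower basal genes as much as the mitotic median of -1.11 in replicates 2 and 3. The 25th percentile of the 24 basal genes there was -0.82 and their median -0.20. Fewer cycling cells would lower G1/S genes alike, and in replicates 2 and 3 the 25th percentile of those 30 genes was -0.44 and their median -0.10. A slide difference remains open, since the list median of replicate 1 on slide 1 was 0.11, inside the range of the controls. A delay before mitosis that differed between the irradiated tissues is a biological hypothesis that could give the same values and was not tested, as slide 2 holds no unexposed tissue.

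The rise of ribosomal protein and cornified layer genes may follow a brightness-dependent difference between arrays. With genes cut into 10 equal groups by brightness, the median difference was 0.27 in the brightest group and between -0.05 and 0.14 in the others. Of 10000 random lists matched on brightness, 79.6% had a median at least as high as that of the ribosomal list and 9.15% as high as that of the granular and cornified list. A brightness trend is thus enough to give the first median and is not excluded for the second. A change in differentiation at 0.5 Gy stays open for the cornified genes, and within slide 1 their median was 0.33 in the single irradiated array.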
